A study of Arabidopsis thaliana with 4 samples.

How the data were processed

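Small RNA reads came from callus of Arabidopsis thaliana Col-0, with 1 library for each of 4 groups (control, nitrogen deficiency, drought and combined). The deposited tables give the raw read count of each distinct sequence in each library, per the file headers. The authors sequenced size-selected inserts of 18 to 40 nt from total RNA on a NextSeq 2000 as single-end reads, per the labels' protocols. The tables hold reads of 15 to 42 nt. Bowtie and DESeq2 1.38.3 were used upstream, per the submitters' processing notes; the aligner's version and settings, the genome build and the trimming steps are not given in the sources used here. Of the 706159, 742947, 594779 and 839182 lines of the 4 tables, 254, 311, 251 and 335 had been emptied and are not analysed here. Deposited quality sheets hold counts of filtered reads by length and RNA class, per the file headers, and have reads at 18 to 26 nt only.

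The authors' deposited comparison tables hold log2 fold changes, per the file headers, and how the log2 values were normalized is not given in the sources used here. They hold linear fold changes (a ratio), deposited beside the log2 column. They hold p-values and adjusted p-values made by the authors; how a p-value was reached with 1 library per group is not given in the sources used here. They hold a column of -log10 adjusted p, as deposited, and a further column whose deposited values are the same as the adjusted p-value, with no rounding or tolerance, in 117 of 117 entries. No p-value was computed from these libraries, and the only error used is counting error.

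Sequences were matched exactly to the 428 mature miRNA names of the RefSeq annotation of TAIR10.1, which hold 350 distinct sequences, and names with the same sequence were counted once. Reads were sorted into classes by exact sense matches, in the order miRNA hairpin, tRNA (with CCA), rRNA, snRNA and snoRNA, then by exact bwa 0.7.19 matches to the organelle and nuclear genome. The rRNA class took in 2100 nt before and 3600 nt after each annotated 5.8S gene. Shares have Clopper-Pearson intervals at 95%. A count of 0 was taken to allow up to 3 reads.

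miRNA counts were scaled with the TMM factors of edgeR 4.0.16 (R 4.3.3) over the 4 libraries. Each of 6 comparisons gives the log2 ratio of scaled counts with an exact conditional (Clopper-Pearson) interval. A miRNA was called higher or lower, or said to have met the size rule, if it had at least 50 reads over the pair, a ratio of 2-fold or more and an interval that excludes a ratio of 1; measured means at least 50 reads over the pair. Departure from additivity was the log2 ratio of combined to control minus the sum of those of the single stresses, with an interval from the Poisson variances of the 4 counts, for miRNAs with at least 50 reads in each pair with the control. For 14 lists covering 42 miRNA families, the median log2 ratio of measured members was placed among 10000 random lists of the same size matched on mean expression in 4 bins, where at least 3 members were measured. Overlaps of calls between comparisons that share a library were set beside the number that independent lists would give and the mean over 1000 simulations with no effect.

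The groups, comparisons, size rule, lists and other settings to be tried were fixed before the data were examined. The rule for named genes took, in each comparison with the control and of the combined library with each single stress, the 10 highest and the 10 lowest miRNAs that met the size rule, up to 4 measured members of each list with the most reads, and the 10 most abundant miRNAs. Those other settings were DESeq2 1.42.0 size factors, total miRNA reads and all clean reads as scaling, minima of 10 and 200 reads and no minimum, each name counted by itself, family totals, and shares of distinct sequences. Counting end variants too (genome-templated reads with ends within 2 nt of the annotated ones), and total miRNA reads and all clean reads as scaling for additivity, were chosen after seeing the data.

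The steps were tested on simulated data drawn from these libraries, with 6 of 140 miRNAs changed 4-fold in each of 50 runs. All changed miRNAs were called (100%) in each comparison with the control. These changes were 4-fold, above the 2-fold of the size rule, and fell on abundant miRNAs only. The 100% therefore does not show how often changes near 2-fold, on counts near 50 reads, would be called. Of unchanged miRNAs, 0.315%, 0.248% and 0.518% were called for nitrogen deficiency, drought and combined stress. Apart from the changes made, with as many miRNAs raised as lowered, the simulated libraries differed by counting error only. These rates therefore leave out variation between libraries and are not rates of false calls in the real comparisons. Intervals covered the simulated ratio in 95.5%, 95.0% and 95.0% of cases. Random lists lay outside the central 95% in 5.5%, 3.5% and 5% of cases. For additivity 100% of miRNAs changed 4-fold were called, with the same limit on what this shows. Of unchanged ones 0.795% were called, and 94.7% of intervals covered, again without variation between libraries. In those runs fewer miRNAs were changed, all of them abundant, and the known library totals served as scaling. TMM scaling of the departures was therefore not tested. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.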

Results

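Small RNA was sequenced from Arabidopsis thaliana Col-0 callus, a mass of dividing cells grown from root explants on auxin (2,4-D at 0.5 mg/L). The 4 groups were control callus, callus without ammonium nitrate (nitrogen deficiency), callus with PEG 8000 at -0.7 MPa (drought) and callus with both (combined), each collected after 7 days. Each group was 1 library, so no difference below has a replicate check, and every ratio compares libraries rather than conditions. The libraries held 12341814 reads (control), 12461652 (nitrogen deficiency), 11815305 (drought) and 14448033 (combined). Exact matches to annotated mature miRNAs made up 17454, 54620, 27542 and 54318 of these reads. A count of 0, which allows up to 3 reads, leaves room for up to 0.0172% of miRNA reads in the control and 0.00549%, 0.0109% and 0.00552% in the other libraries, in the same order. Intervals and these floors cover counting error only, and all are 95% intervals.

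miRNA precursors held a larger share of reads in every stressed library than in the control. Their share of distinct sequences was 0.249% in the control and 0.306%, 0.295% and 0.243% under nitrogen deficiency, drought and combined stress, the last below the control. Reads within annotated miRNA hairpins were 0.419% of the control library (Clopper-Pearson interval 0.415 to 0.422), 1.39% under nitrogen deficiency (1.381 to 1.394), 0.815% under drought (0.810 to 0.820) and 1.04% under combined stress (1.03 to 1.04). That share was 3.31 times the control's under nitrogen deficiency (interval 3.28 to 3.35), 1.95 times under drought (1.92 to 1.97) and 2.48 times under combined stress (2.46 to 2.51). tRNA fragments took 41.0% of control reads and 29.3%, 35.9% and 31.8% of reads under nitrogen deficiency, drought and combined stress. rRNA fragments took 27.7% of control reads and 16.6%, 20.5% and 26.4% in the same order. snRNA and snoRNA fragments were 3.58% of control reads and 5.89%, 5.77% and 8.42% of the stressed libraries. Among reads of 18 to 26 nt the directions differed: tRNA was 6.67% in the control and 7.50%, 9.94% and 8.56% in the stressed libraries, and snRNA and snoRNA 3.33% and 2.56%, 2.26% and 2.07%, while miRNA hairpins were 1.85% and 6.05%, 4.01% and 3.81%. Per 24-nt read elsewhere in the nuclear genome, miRNA hairpin reads were 1.71 times the control's under nitrogen deficiency and 2.12 times under drought, but 0.937 times (0.926 to 0.948) under combined stress. The most common read length was 33 nt in the control and 16 nt in the other libraries. 24-nt reads, the length class of heterochromatic siRNAs, were 3.59% of control reads, 3.84% under nitrogen deficiency, 2.60% under drought and 5.56% under combined stress. In the same order, 54.3%, 27.3%, 44.5% and 33.8% of these 24-nt reads were rRNA fragments. Those that matched the nuclear genome outside annotated small RNA genes numbered 141760, 277272, 124374 and 439348. Among 24-nt reads that matched the nuclear genome outside annotated small RNA genes, those beginning with A made up 49.3% in the control and 58.3%, 55.3% and 56.2% in the stressed libraries. Of 21-nt reads from miRNA hairpins, 91.7%, 90.7%, 90.7% and 93.3% began with T, the usual start of plant miRNAs.

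**Figure D1:**
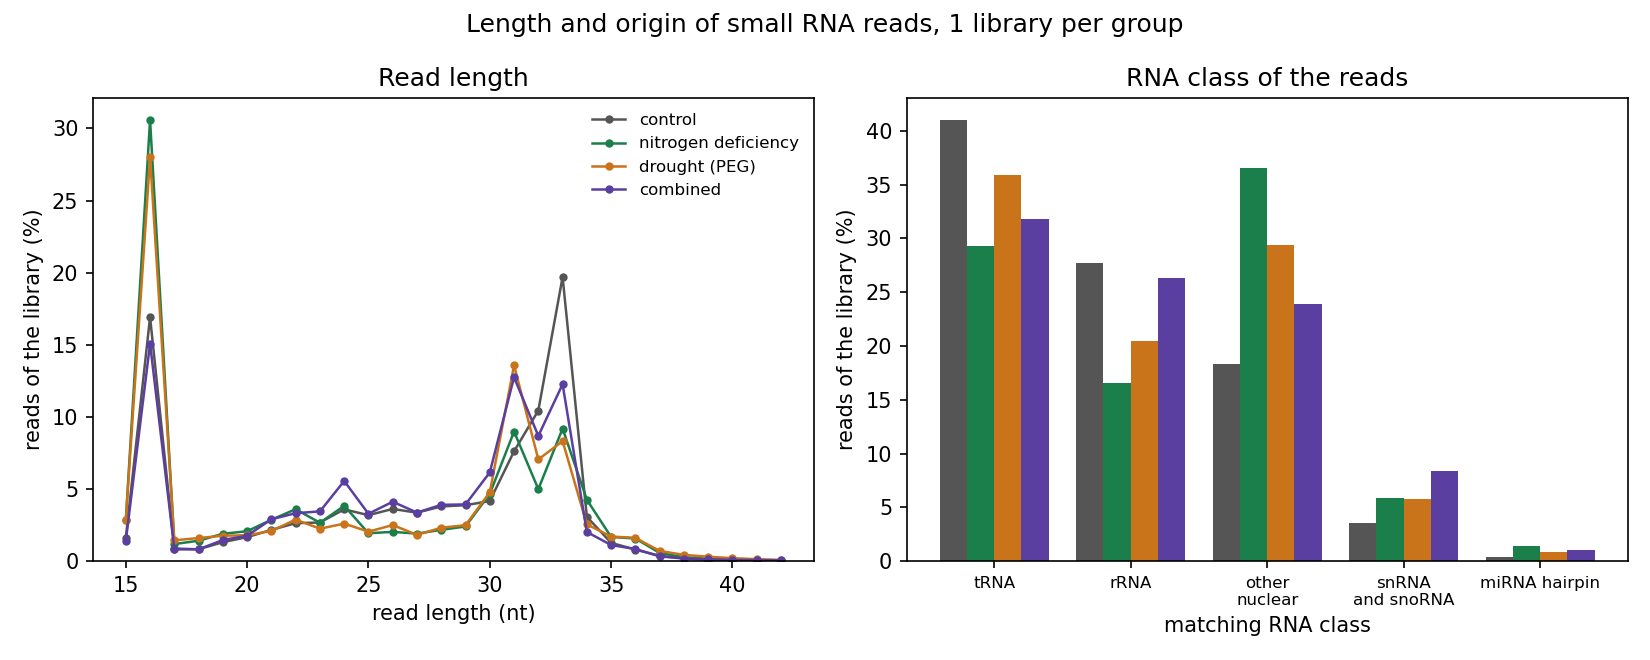
Read length in nt against percent of the library's reads (left, 1 line per library), and percent of reads that matched each RNA class (right, 1 bar per library). The control peaks at 33 nt with 19.7% of its reads, while 16-nt reads reach 30.6% under nitrogen deficiency and 28.0% under drought.

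A small number of miRNAs supplied most of the miRNA reads. The 10 most abundant sequences were miR158a-3p, miR403-3p, miR396a-5p, miR159a, miR827, miR161.1, miR846-3p, miR398b-3p/miR398c-3p, miR158b and miR159b-3p, and together they held 85.8% of 153934 exact reads. miR158a-3p, from MIR158a on chromosome 3 (3366349 to 3366368, minus strand), was the most abundant in all 4 libraries, at 20.7%, 25.2%, 30.2% and 20.3% of miRNA reads. Of 350 distinct mature sequences in the annotation, 140 had a read in at least 1 library, and 52 had at least 50 reads over the 4 libraries. Of the lists of families fixed beforehand, the sulfate starvation list had 0 members with at least 50 reads in any comparison, miR827 was the only measured member of the phosphate starvation list, and miR826a the only 1 of the glucosinolate list.

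Nitrogen deficiency against the control asked which miRNAs differ when ammonium nitrate is left out. miR826a, which targets the glucosinolate gene AOP2, was higher by a log2 ratio of 2.43 (interval 1.00 to 4.34; 65 against 4 reads). miR857, which targets a laccase, was higher by 1.28 (0.04 to 2.80). miR158a-5p was higher by 1.28 (0.76 to 1.84), and miR167a-5p/miR167b, which targets auxin response factors, by 1.01 (0.15 to 1.98). miR827, which acts on the phosphate regulator NLA, was lower with a log2 ratio of -1.05 (-1.14 to -0.96; 2437 against 1666 reads) and miR5026 with -1.01 (-1.74 to -0.27), except that with scaling to all clean reads all 15 negative ratios turned positive, these to 0.53 and 0.57. These 4 higher and 2 lower miRNAs were among 39 with at least 50 reads over the pair. MIR826a lies on chromosome 4 (1340528 to 1340548, plus strand, TAIR10.1), MIR857 on chromosome 4 (7878198 to 7878218, minus strand) and MIR827 on chromosome 3 (22122811 to 22122831, minus strand).

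Families known from nitrogen-starved seedlings to rise had 3 measured members, of which miR826a was higher, while miR846-3p had a log2 ratio of 0.09 (-0.03 to 0.21) and the miR160 group, which targets auxin response factors, 0.56 (-0.26 to 1.48). Families known to fall there had 5 measured members: miR827 was lower and miR857, also counted among the copper-linked families, was higher. The remaining 3 had log2 ratios of 0.03 (miR398b-3p/miR398c-3p, which targets copper superoxide dismutases), -0.07 (miR408-3p, which targets plantacyanin) and 0.05 (miR408-5p). The copper-linked list therefore held 4 measured members, with 1 higher. In the auxin response list, 1 of 4 measured members was higher, and in the nitrate signalling list, which shares its miR167 sequences, 1 of 3; their other members included miR167c-5p at 0.37 (-0.30 to 1.10) and miR167c-3p at -0.06 (-0.43 to 0.32). None of the 8 measured members of the drought and ABA list met the size rule, where miR159a stood at -0.58 (-0.65 to -0.50; 1.01 with all clean reads) and miR159b-3p at -0.59 (-0.74 to -0.45). None of the 3 developmental timing members, 8 meristem and organ patterning members, 4 members of the families that act on DCL1 and AGO genes, or 2 secondary siRNA triggers met it. The 9 lists with at least 3 measured members all had medians inside the central 95% of random lists. Higher and lower miRNAs numbered 2 and 2 with scaling to total miRNA reads and 34 and 0 with scaling to all clean reads. With end variants counted, an alternative chosen after seeing the data, 10 were higher and 4 lower, including 3 of the 4 higher and 0 of the 2 lower named above, and miR857 and miR167a-5p/miR167b fell short with total miRNA reads (1.23, with an interval that includes 0, and 0.96), the latter with DESeq2 factors (0.98) as well.

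Drought against the control asked which miRNAs differ under PEG. miR158a-5p was higher with a log2 ratio of 1.58 (interval 1.03 to 2.17; 145 against 34 reads), as was miR167a-5p/miR167b with 1.07 (0.14 to 2.10; 39 against 13 reads). miR822-3p was lower with -1.42 (-2.17 to -0.71; 26 against 49 reads), and miR159b-3p, which targets GAMYB-like transcription factors, with -1.04 (-1.22 to -0.86; 418 against 603 reads). MIR158a lies on chromosome 3 (its 5p arm at 3366391 to 3366411, minus strand), MIR159b on chromosome 1 (6220813 to 6220833, plus strand) and MIR822 on chromosome 5 (897067 to 897087, minus strand). These 2 higher and 2 lower miRNAs were among 32 measured.

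In the drought and ABA list, 1 of 5 measured members was lower (miR159b-3p), and the others were miR159a at -0.80 (-0.89 to -0.71), miR319a/miR319b at -0.70 (-1.06 to -0.34), miR396a-5p, which targets growth-regulating factors, at -0.30 (-0.38 to -0.22; 0.27 with all clean reads) and miR396b-5p at 0.75 (0.50 to 1.01). Its median of -0.70 lay at the 4.19 percentile of random lists, inside their central 95%. The cell wall and MYB list had 2 measured members, miR159a and miR159b-3p. None of the 3 members acting on DCL1 and AGO genes met the size rule; miR403-3p, which targets AGO2, stood at 0.61 (0.54 to 0.67) and miR162a-3p/miR162b-3p, which targets DCL1, at 0.68 (0.48 to 0.89). The 4 measured members of the list that falls under nitrogen starvation had a median of -0.48, with miR827 at -0.74 (-0.85 to -0.64), and none met the rule; the 3 copper-linked members had a median of -0.45. The developmental timing list had 3 measured members with a median of 0.58, led by the miR156 group of SPL-targeting miRNAs at 0.82 (0.44 to 1.22). That median is the value of miR157a-5p/miR157b-5p/miR157c-5p (-0.15 to 1.34), which turned to -0.17 with end variants. Nitrate signalling and auxin response each had 3 measured members with 1 higher, the 6 patterning members had a median of -0.25, the 2 siRNA triggers miR161.1 and miR173-5p stood at 0.30 and -0.74, and miR846-3p was the only measured member of the list that rises under nitrogen starvation, at 0.21. All 8 lists with at least 3 measured members lay inside the central 95% of random lists. Higher and lower miRNAs numbered 2 and 1 with DESeq2 factors, 1 and 2 with total miRNA reads and 10 and 0 with all clean reads. miR159b-3p fell short with DESeq2 factors (-0.90), with all clean reads (-0.47) and with end variants (-0.47), miR822-3p with all clean reads (-0.85), and miR167a-5p/miR167b with total miRNA reads (0.93).

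Combined stress against the control addressed the main question of the series, which miRNAs accompany nitrogen deficiency and drought together. miR826a was higher with a log2 ratio of 3.74 (interval 2.35 to 5.63; 136 against 4 reads), miR167a-5p/miR167b with 2.21 (1.39 to 3.15; 153 against 13 reads) and miR857 with 1.74 (0.52 to 3.25; 51 against 6 reads). miR845b, known to target retrotransposons, was higher with 1.65 (1.19 to 2.14; 352 against 44 reads), and miR161.1, which targets pentatricopeptide repeat genes, with 1.14 (1.02 to 1.26; 3778 against 672 reads). miR866-3p and miR167c-5p were higher with 1.06 each (intervals 0.26 to 1.97 and 0.41 to 1.77). miR5026 was lower with -1.30 (-2.10 to -0.50; 29 against 28 reads). MIR845b lies on chromosome 4 (12214086 to 12214107, minus strand), MIR161 on chromosome 1 (17825731 to 17825751, plus strand), and the miR167a-5p/miR167b sequence comes from MIR167a and MIR167b on chromosome 3 (8108090 to 8108110 and 23406177 to 23406197, plus strand). The 38 measured miRNAs had a median log2 ratio of 0.40, with 7 higher and 1 lower.

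In the nitrate signalling list 2 of 3 measured members were higher (miR167a-5p/miR167b and miR167c-5p), and miR167c-3p stood at 0.74 (0.39 to 1.11); its median of 1.06 lay at the 94.4 percentile of random lists. The auxin response list adds the miR160 group at 0.77 (-0.06 to 1.68), giving 2 of 4 higher. In the list that rises under nitrogen starvation miR826a was higher, and miR846-3p, which targets jacalin lectin genes, stood at 0.70 (0.59 to 0.82). In the list that falls there, 1 of 5 was higher (miR857), and miR827 stood at -0.41 (-0.50 to -0.32; 0.71 with all clean reads). The drought and ABA list had 6 measured members, none meeting the size rule, with a median of 0.08 at the 2.31 percentile of random lists, which is outside their central 95%. Its members miR159a, miR159b-3p, miR396a-5p and miR319a/miR319b stood between 0.04 and 0.08, below the median of all measured miRNAs (and below 0 with DESeq2 factors and with total miRNA reads), and miR396b-5p stood at 0.62 (0.38 to 0.87). The miR156 group stood at 1.00 (0.65 to 1.36), just short of 2-fold, and miR403-3p at 0.54 (0.48 to 0.61). Among secondary siRNA triggers 1 of 3 was higher (miR161.1), while miR472-3p stood at 0.09 (-0.71 to 0.96) and miR173-5p, which targets TAS transcripts, at -0.83 (-1.23 to -0.42; 0.30 with all clean reads). Of 4 copper-linked members 1 was higher, and none of the 3 timing, 5 patterning or 4 DCL1 and AGO members met the size rule. The drought and ABA list was the only one of 10 outside the central 95% of random lists, and it lay inside with a minimum of 10 reads (11.7 percentile) and with family totals (6.58 percentile). Random lists lie outside at a rate of about 5%, so 1 list of 10 can arise by chance. Higher and lower miRNAs numbered 4 and 1 with DESeq2 factors, 4 and 2 with total miRNA reads and 33 and 0 with all clean reads. miR161.1, miR866-3p and miR167c-5p fell short with the DESeq2 factors (0.97, 0.89 and 0.89) and with total miRNA reads (0.85, 0.78 and 0.77), miR5026 fell short with all clean reads (-0.18) and, with end variants, miR167c-5p (0.96) and miR5026 (-0.97) did.

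**Figure D2:**
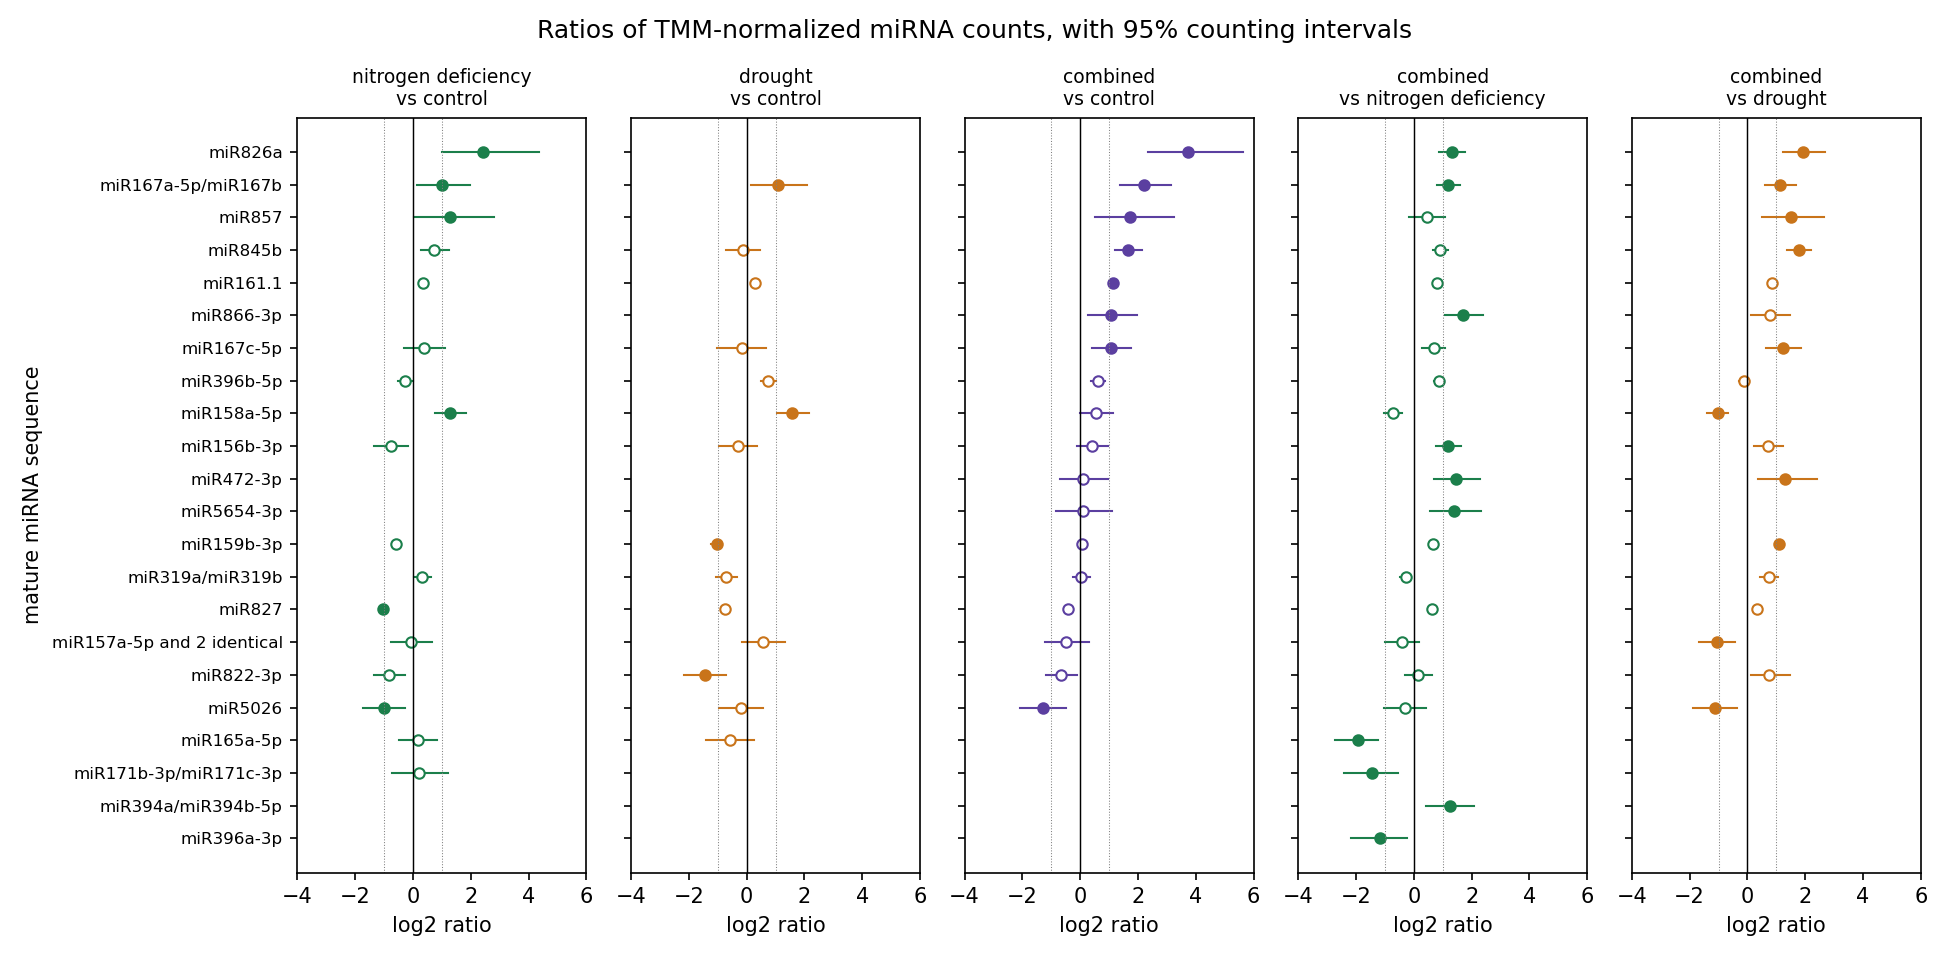
Log2 ratio of TMM-normalized counts (horizontal axis, log2 units) for each miRNA that met the size rule in at least 1 of the 5 comparisons drawn or in drought against nitrogen deficiency; points are ratios, bars are 95% counting intervals, filled points met the rule, dotted lines mark 2-fold, and pairs with under 50 reads are left out. miR826a reaches 3.74 and miR167a-5p/miR167b 2.21 in combined against control; with scaling to all clean reads every negative point in nitrogen deficiency against control turns positive (miR827 to 0.53, miR5026 to 0.57).

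Calls shared by comparisons with a common library were set beside simulated libraries that differ by counting error only, so that variation between libraries, which was not measured, is not in the simulated numbers. Nitrogen deficiency and combined stress shared 3 higher miRNAs relative to the control (miR826a, miR857 and miR167a-5p/miR167b), where the simulation gave 0.052 and independent lists would give 0.686. They shared 1 lower miRNA, miR5026, against 0.009 simulated and 0.0571 for independent lists. Nitrogen deficiency and drought shared 2 higher miRNAs (miR158a-5p and miR167a-5p/miR167b; 0.01 simulated, 0.125 independent), and drought and combined stress shared miR167a-5p/miR167b (0.007 and 0.258). Among miRNAs with at least 50 reads in each pair with the control, which leaves out miR826a (20 reads in drought against 4), miR167a-5p/miR167b alone was higher than the control in all 3 stressed libraries. It had 13 control reads and fell short in nitrogen deficiency and drought with total miRNA reads (0.96 and 0.93), so part of any excess may come from the shared control library.

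Combined stress against nitrogen deficiency set libraries with and without PEG side by side, both without ammonium nitrate. miR866-3p was higher with a log2 ratio of 1.71 (interval 1.08 to 2.38), miR472-3p, which targets NLR disease resistance genes, with 1.47 (0.70 to 2.28), miR5654-3p with 1.41 (0.55 to 2.32) and miR826a with 1.31 (0.87 to 1.76). miR394a/miR394b-5p, which targets the F-box gene LCR, was higher with 1.25 (0.44 to 2.10), miR167a-5p/miR167b 2.30-fold (1.74 to 3.05) and miR156b-3p by a log2 ratio of 1.19 (0.76 to 1.63). miR165a-5p, the passenger arm of a hairpin whose other arm targets HD-ZIP III genes, was lower with -1.94 (-2.72 to -1.23; 20 against 91 reads). miR171b-3p/miR171c-3p, which targets the HAM genes of the shoot meristem, was lower with -1.44 (-2.42 to -0.55), and miR396a-3p with -1.16 (-2.16 to -0.23). MIR866 lies on chromosome 5 (16157838 to 16157857, minus strand), MIR472 on chromosome 1 (4182143 to 4182164, minus strand) and the miR165a-5p arm on chromosome 1 (79010 to 79030, minus strand). The 7 higher and 3 lower miRNAs were among 50 measured, whose median log2 ratio was 0.33.

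All 3 lower miRNAs belonged to the meristem and organ patterning list, in which 3 of 9 measured members were lower and 0 higher. Its median of -0.28 lay at the 1.75 percentile of random lists, the only 1 of 10 lists outside their central 95%, and with family totals it lay inside, at the 2.77 percentile. At a rate of about 5% for random lists, 1 of 10 can arise by chance here too. Abundant patterning members included miR319a/miR319b at -0.28 (-0.48 to -0.09) and the miR166 group, which targets HD-ZIP III genes, at 0.52 (0.36 to 0.69). miR396a-5p stood at 0.04 (-0.01 to 0.09, or -0.41 with all clean reads) and miR396b-5p at 0.88 (0.71 to 1.06). Lists went by family number, so both arms of a hairpin counted. The lower miR165a-5p and miR396a-3p are the arms opposite to miR165a-3p/miR165b, at 0.36 (0.14 to 0.58), and miR396a-5p. The drought and ABA list had 11 measured members, 1 higher (miR394a/miR394b-5p) and 2 lower (miR171b-3p/miR171c-3p and miR396a-3p), with miR159a at 0.65 (0.59 to 0.71). The list that rises under nitrogen starvation had 4 measured members, with miR826a higher and miR846-3p at 0.62 (0.54 to 0.69). None of the 5 members of the list that falls there met the size rule, with miR827 at 0.64 (0.56 to 0.71). Nitrate signalling had 1 of 3 and auxin response 1 of 4 higher (miR167a-5p/miR167b), developmental timing 1 of 3 (miR156b-3p) and siRNA triggers 1 of 3 (miR472-3p), with miR161.1 at 0.79 (0.71 to 0.86). The miR156 group, from the arm opposite to miR156b-3p, stood at 0.34 (0.14 to 0.55). None of 5 DCL1 and AGO members and none of 4 copper-linked members met the size rule. With all clean reads the split became 2 higher and 4 lower, and miR826a (0.85), miR167a-5p/miR167b (0.74), miR156b-3p (0.73), miR394a/miR394b-5p (0.79) and miR5654-3p (0.95) fell short. With total miRNA reads miR156b-3p (0.95) and miR167a-5p/miR167b (0.96) fell short, and with end variants miR396a-3p stood at -0.87 and miR156b-3p at 0.96, while miR168b-3p turned from 0.06 to -1.39.

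Combined stress against drought set libraries without and with ammonium nitrate side by side, both under PEG. miR826a was higher with a log2 ratio of 1.93 (interval 1.24 to 2.68), miR845b 3.45-fold (2.60 to 4.65), miR857 by a log2 ratio of 1.51 (0.52 to 2.65) and miR472-3p with 1.32 (0.35 to 2.41). miR167c-5p was higher with 1.23 (0.64 to 1.87), miR167a-5p/miR167b with 1.13 (0.62 to 1.68) and miR159b-3p with 1.11 (0.95 to 1.26; 1609 against 418 reads). miR5026 was lower with -1.11 (-1.87 to -0.36), miR157a-5p/miR157b-5p/miR157c-5p, which targets SPL genes, with -1.05 (-1.67 to -0.44) and miR158a-5p with -1.03 (-1.39 to -0.68). The 7 higher and 3 lower miRNAs were among 40 measured, whose median log2 ratio was 0.53. miR826a, miR845b, miR857, miR167a-5p/miR167b and miR167c-5p, 5 of these 7, were also among the 7 higher in combined stress against the control, a pair of comparisons that share the combined library (0.004 simulated, 1.32 for independent lists). Against nitrogen deficiency and against drought the combined library shared 3 higher miRNAs (miR826a, miR167a-5p/miR167b and miR472-3p), again with that library in common (0.004 simulated, 0.875 for independent lists).

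Nitrate signalling had 2 of 3 measured members higher and auxin response 2 of 4, with the miR160 group at 0.93 (0.18 to 1.76), or -0.12 with end variants. The list that rises under nitrogen starvation had 1 of 3 higher (miR826a), and miR846-3p stood at 0.49 (0.40 to 0.59). The list that falls there had 1 of 5 higher (miR857), miR398b-3p/miR398c-3p at 0.60 (0.46 to 0.75), miR408-3p at 0.59 (0.36 to 0.83) and miR827 at 0.33 (0.24 to 0.42). The drought and ABA list had 1 of 6 higher (miR159b-3p), with miR159a at 0.87 (0.80 to 0.95). miR159b-3p and miR159a were the only measured members of the cell wall and MYB list. Of 3 timing members 1 was lower, and miR156b-3p stood at 0.72 (0.23 to 1.25). None of 5 patterning or 4 DCL1 and AGO members met the size rule, with miR403-3p at -0.06 (-0.11 to -0.01) and miR162a-3p/miR162b-3p at -0.31 (-0.45 to -0.16), which turned to 0.49 and 0.24 with all clean reads. No list of the 10 lay outside the central 95% of random lists. Higher and lower miRNAs numbered 4 and 3 with DESeq2 factors and 22 and 0 with all clean reads, which left miR158a-5p at -0.48, miR157a-5p/miR157b-5p/miR157c-5p at -0.50 and miR5026 at -0.56. miR159b-3p (0.80), miR167a-5p/miR167b (0.82) and miR167c-5p (0.92) fell short with DESeq2 factors, the former 2 also with total miRNA reads (0.96 and 0.99), and end variants left all 3 short (0.78, 0.52 and 0.82), with miR857 at 0.81 and miR5026 at -0.91, and turned miR168b-3p from 0.31 to -1.199.

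Drought against nitrogen deficiency set the single stresses side by side, with 1 miRNA higher and 2 lower among 42. These 3 lie outside the naming rule set beforehand and were named after their values were seen. miR396b-5p was higher with a log2 ratio of 1.01 (interval 0.82 to 1.21), while miR857 was lower with -1.05 (-2.21 to -0.04) and miR319a/miR319b, which targets TCP genes, with -1.02 (-1.32 to -0.74). miR826a stood at -0.61 (-1.42 to 0.13) on 20 against 65 reads. The medians of the lists that fall and rise under nitrogen starvation were -0.47 and -0.61, at the 3.85 and 3.48 percentiles, and none of 9 lists lay outside the central 95% of random lists. The split was 4 and 0 with DESeq2 factors, 0 and 2 with total miRNA reads and 0 and 20 with all clean reads. miR319a/miR319b (-0.86) and miR857 (-0.89) fell short with the DESeq2 factors, and miR396b-5p with total miRNA reads (0.92), all clean reads (0.00) and end variants (0.85), which also left miR857 at -0.55.

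Whether combined stress equals the sum of the single stresses was asked for 31 miRNAs with at least 50 reads in each pair with the control. Their departures from that sum had a median of 0.42 on the log2 scale. Those of 6 miRNAs were 2-fold or more above it: miR159b-3p by 1.70 (interval 1.49 to 1.91), miR822-3p by 1.58 (0.77 to 2.40), miR156b-3p by 1.497 (0.75 to 2.24), miR159a by 1.45 (1.34 to 1.56), miR827 by 1.381 (1.25 to 1.51) and miR845b by 1.05 (0.44 to 1.67). The miR156 group, from the arm opposite to miR156b-3p, did not lie above the sum. Its log2 ratios to control were 0.65 under nitrogen deficiency, 0.82 under drought and 1.00 under combined stress. For miR158a-5p the combined library lay below the sum, with a departure of -2.31 (-2.93 to -1.69): its log2 ratio to control was 1.28 under nitrogen deficiency, 1.58 under drought and 0.55 (-0.00 to 1.14) under combined stress. The opposite and far more abundant arm of that hairpin, miR158a-3p, had smaller log2 ratios of 0.34, 0.69 and 0.26 in the same order. miR159a had log2 ratios of -0.58, -0.80 and 0.07 in the same order, and miR827 of -1.05, -0.74 and -0.41. miR167a-5p/miR167b lay near the sum, with a departure of 0.13 (-0.86 to 1.11). miR826a was left out because its reads in drought and control together were under 50. With all clean reads, an alternative chosen after seeing the data, 0 miRNAs lay above the sum and 10 below, and with DESeq2 factors 5 and 3. The TMM factor of the combined library was 0.891 for these counts, 1.097 with each name by itself and 1.099 with family totals. A lower factor for that library raises every departure alike, so the median of 0.42 depends on the scaling. miR845b fell short with DESeq2 factors (0.77) and with total miRNA reads (0.96), and end variants left it at 0.77 and miR159b-3p at 0.90.

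**Figure D3:**
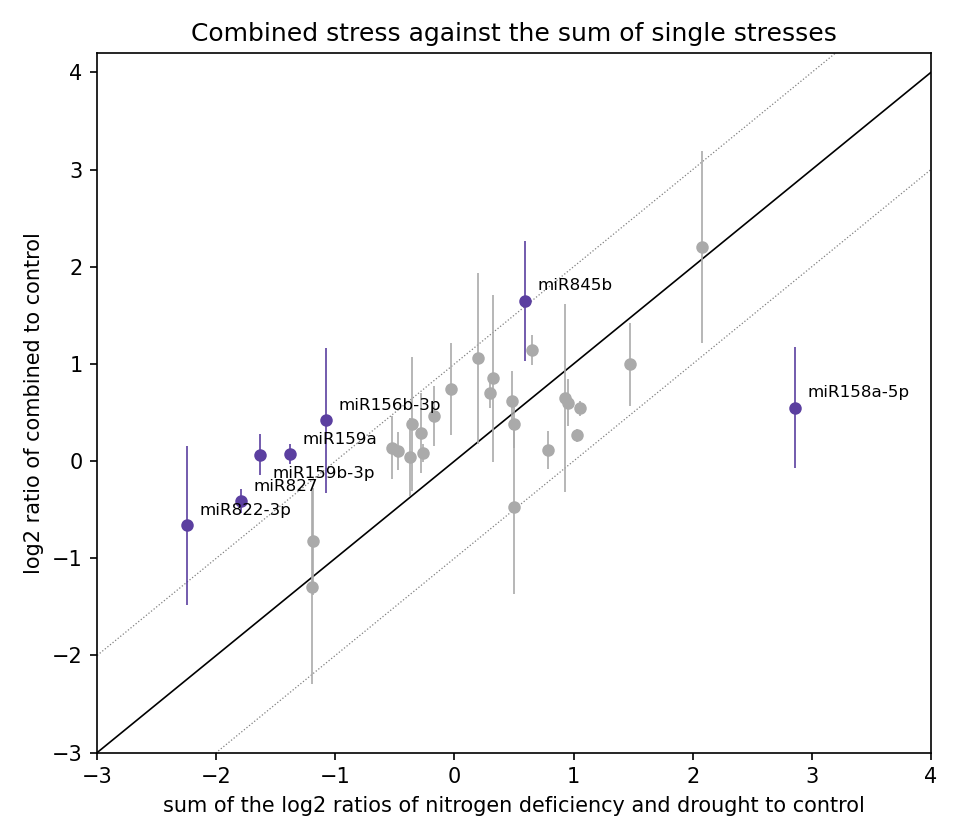
Sum of the log2 ratios of nitrogen deficiency and drought to control (horizontal) against the log2 ratio of combined stress to control (vertical), 1 point per miRNA with at least 50 reads in each pair with the control, 31 in all; bars are 95% counting intervals of the departure from the sum, the solid line marks equality, dotted lines mark 2-fold, and named points met the size rule. With TMM factors 6 points lie above the band and miR158a-5p lies below it at a departure of -2.31; with all clean reads 0 lie above.

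The submitters' own comparisons covered the same 6 pairs. The authors' deposited tables list 117 entries, 67 as up and 50 as down, all from 12 families that run from miR156 to miR167. The names miR826a, miR857, miR845b, miR827 and miR866-3p are therefore absent from the authors' deposited tables. Their listing as up or down does not always match the sign, since miR159a for control and drought is listed as up with a negative log2 value. Of 112 entries with reads here, 58 had the same sign as the ratio computed from the counts, second library over the other (51.8%, interval 42.1 to 61.3). The other 54 had the opposite sign. That interval treats the entries as independent and does not express counting error. Names recur across comparisons that share libraries, and some names share the same reads, so it is too narrow. Which library is the numerator is not stated in the authors' deposited tables, so neither count settles the direction. In the authors' deposited tables, names are in alphabetical order when entries are sorted by p-value (98 of 98 neighbouring pairs), so which value belongs to which name is open, and the count of matching signs rests on names and values as paired there. For control and combined, miR160a, miR160b and miR160c, which have the same reads here, carry log2 values of -1.07, 2.36 and 7.40. miR156j is listed in 5 comparisons and had 0 reads here in every library. The miRNA reference behind the authors' values is not given in the sources used here.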

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

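For the results in this part, both the test against the choice of scaling and the test on end variants were chosen after the result was seen. For 4 miRNAs PEG went with ratios of opposite sign with and without nitrogen deficiency that both had an interval excluding 0 and that differed 2-fold or more, and the difference was not tested, since each group has 1 library. Further miRNAs changed sign without meeting these limits. miR159b-3p had a log2 ratio of -1.04 for PEG alone and 0.66 for PEG on top of nitrogen deficiency, a difference of 1.70; miR159a had -0.80 and 0.65, a difference of 1.45; and miR827 had -0.74 and 0.64, a difference of 1.381. miR158a-5p went the other way, with 1.58 and -0.73, a difference of -2.31. The opposite and far more abundant arm of its hairpin, miR158a-3p, had 0.69 (0.64 to 0.75) and -0.07 (-0.11 to -0.03).

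The signs stayed opposite for all 4 under every scaling tried, so what the choice of scaling factors leaves open is the size: with all clean reads, 2 of the 4 differed by less than 1.5 times (miR159a by 0.42, interval 0.31 to 0.52, and miR827 by 0.35, 0.22 to 0.47), while miR159b-3p stood at 0.67 and miR158a-5p at -3.34. No single factor per library can move all 4 to 0, because miR158a-5p and miR159b-3p lie 4.01 log2 units apart. A shift between the annotated sequence and end variants is argued against as the whole cause for 3 of the 4. Their end variants alone differed in the same direction by 1.5 times or more. The differences were 6.27-fold for miR159a (log2 interval 1.24 to 4.05), 1.94-fold for miR827 (0.38 to 1.54) and 4.26-fold for miR158a-5p (-3.09 to -1.09). They rest on few reads, 9 to 53 per library for miR159a, 78 to 142 for miR827 and 18 to 76 for miR158a-5p. End variants of miR159b-3p, with 534 to 1404 reads per library, differed by 1.30-fold, so such a shift stays open there. An effect of PEG that depends on nitrogen supply, as an untested biological hypothesis, may remain for all 4, and so do differences between libraries that no replicate separates from the treatments.

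The deposited quality sheet assigned 5 reads of the nitrogen deficiency library to miRNAs of primates, against 1 in the control, 0 in drought and 2 in combined stress, in data that the comparisons do not use; the difference was not tested. The floor for such counts was 3 reads. Reads assigned to miRNAs of dicots numbered 57273 under nitrogen deficiency, 16690 in the control, 32063 in drought and 58762 in combined stress.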

How the results depend on the processing

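The alternatives with end variants, and those with total miRNA reads and all clean reads for additivity, were chosen after the result was seen. No paired analysis was possible because each group has 1 library, which also rules out leaving a replicate out. Between 17454 and 54620 miRNA reads per library limit the comparisons to 32 to 50 miRNAs. Of the values for single miRNAs, 68.1% stayed on the same side of the size rule or within their interval with DESeq2 factors, 65.1% with total miRNA reads, 23.5% with all clean reads and 60.8% with end variants; of list percentiles, 96.4% did so with a minimum of 10 and 93.9% with family totals. Another minimum cannot move the ratios that remain, nor total miRNA reads a list's percentile. Relative to TMM, all clean reads shifted the median log2 ratio by 1.58 (nitrogen deficiency against control), 0.57 (drought against control), 1.12 (combined against control), -0.46 (combined against nitrogen deficiency), 0.55 (combined against drought) and -1.01 (drought against nitrogen deficiency). In the same order DESeq2 factors shifted it by -0.02, 0.14, -0.17, -0.15, -0.31 and 0.16, total miRNA reads by -0.05, -0.15, -0.29, -0.24, -0.14 and -0.10, and end variants by 0.28, 0.17, 0.23, -0.05, -0.02 and -0.08. A minimum of 200 tests fewer miRNAs, and a minimum of 10 or none tests more. The TMM factor of the combined library rose from 0.891 to 1.097 with each name by itself and to 1.099 with family totals. That lowers its ratios to the other libraries, but these settings also regroup the counts, and the effects were not separated. For the other values below the cause was not tested.

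For nitrogen deficiency against control (4 higher, 2 lower), the number higher was 2 with total miRNA reads, 34 with all clean reads, 1 with a minimum of 200 and 10 with end variants, and the number lower was 0 with all clean reads, 6 with a minimum of 10, 7 with no minimum, 1 with a minimum of 200, 1 with each name by itself, 0 with family totals and 4 with end variants. For drought against control (2 higher, 2 lower), the number higher was 1 with total miRNA reads, 10 with all clean reads, 5 with a minimum of 10, 7 with no minimum, 0 with a minimum of 200, 1 with family totals and 7 with end variants, and the number lower was 1 with DESeq2 factors, 0 with all clean reads, 7 with a minimum of 10, 7 with no minimum and 1 with a minimum of 200. For combined against control (7 higher, 1 lower), the number higher was 4 with DESeq2 factors, 4 with total miRNA reads, 33 with all clean reads, 2 with a minimum of 200 and 3 with family totals, and the number lower was 2 with total miRNA reads, 0 with all clean reads, 6 with a minimum of 10, 7 with no minimum, 0 with a minimum of 200, 3 with each name by itself, 3 with family totals and 7 with end variants. For combined against nitrogen deficiency (7 higher, 3 lower), the number higher was 2 with all clean reads, 3 with a minimum of 200, 2 with each name by itself and 2 with family totals, and the number lower was 6 with a minimum of 10, 8 with no minimum, 0 with a minimum of 200, 5 with each name by itself and 7 with end variants. For combined against drought (7 higher, 3 lower), the number higher was 4 with DESeq2 factors, 22 with all clean reads, 2 with a minimum of 200, 3 with each name by itself and 2 with family totals, and the number lower was 0 with all clean reads, 7 with a minimum of 10, 10 with no minimum, 1 with a minimum of 200, 6 with each name by itself and 5 with end variants. For drought against nitrogen deficiency (1 higher, 2 lower), the number higher was 4 with DESeq2 factors, 0 with total miRNA reads, all clean reads, each name by itself, family totals and end variants, 2 with a minimum of 10 and 6 with no minimum, and the number lower was 0 with DESeq2 factors, 20 with all clean reads, 4 with a minimum of 10, 4 with no minimum and 1 with a minimum of 200. For additivity (6 above the sum, 1 below), the number above was 3 with a minimum of 200, 3 with family totals and 0 with all clean reads, and the number below was 3 with DESeq2 factors, 0 with a minimum of 200, 4 with family totals, 9 with end variants, 2 with total miRNA reads and 10 with all clean reads. Lists outside the central 95% of random lists numbered 0 with a minimum of 10 and with family totals for combined against control (1 otherwise), 2 with a minimum of 10 for combined against drought (0 otherwise), 1 with family totals for drought against control (0 otherwise) and 0 with family totals for combined against nitrogen deficiency (1 otherwise).

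The shift with all clean reads applies to every miRNA alike and turned all 15 negative log2 ratios of nitrogen deficiency to control positive, 11 of 17 for drought to control, 4 of 5 for combined to control and 6 of 11 for combined to drought, and turned 17 of 36 positive ratios of combined to nitrogen deficiency and 21 of 22 of drought to nitrogen deficiency negative. For nitrogen deficiency against control, the named miRNAs that changed sign and were called before or after the shift were miR159a (1.01), miR827 (0.53), miR162a-3p/miR162b-3p (1.40), miR396b-5p (1.32), the miR166 group (1.52), miR408-3p (1.51), miR167c-3p (1.52), miR173-5p (1.14), miR157a-5p/miR157b-5p/miR157c-5p (1.51) and miR5026 (0.57). With end variants miR168b-3p turned negative against nitrogen deficiency (-1.39) and against drought (-1.199) in the combined library. Others that turned included the miR160 group (0.93 to -0.12) and the miR156 group (0.17 to -0.61) in combined against drought. In drought against control miR157a-5p/miR157b-5p/miR157c-5p turned from 0.58 to -0.17. As shares of distinct sequences in control, nitrogen deficiency, drought and combined, 21-nt reads were 6.29%, 6.99%, 6.56% and 5.98%, 24-nt reads 12.2%, 17.4%, 11.965% and 21.5%, miRNA hairpins 0.249%, 0.306%, 0.295% and 0.243%, tRNA 1.00%, 0.805%, 0.946% and 0.772%, and rRNA 14.1%, 10.9%, 14.8% and 11.3%.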

Other observations

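The tests in this part, on the miRNA share of reads and on the order of names in the authors' tables, were chosen after the results were seen. Fragments from the 5′ end of tRNAs made up 93.5% of tRNA reads in the control and 85.8%, 87.4% and 88.5% under nitrogen deficiency, drought and combined stress. Glutamate tRNA gave 64.0% of tRNA reads in the control and 44.1%, 41.5% and 54.1% in the stressed libraries, while glycine tRNA gave 19.1% in the control and 34.6%, 46.7% and 38.7%. A 33-nt 5′ fragment of tRNA-Glu(TTC), from AT1G09110 and other copies, took 12.7% of all control reads and 5.74%, 5.13% and 8.20% of the others, and a 31-nt 5′ fragment of tRNA-Gly(TCC) took 3.33%, 4.10%, 8.15% and 4.78%. A 16-nt fragment of tRNA-Ala(AGC) was 0.234 times as frequent under combined stress as in the control (0.797% against 3.41% of reads).

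A 31-nt fragment of the snoRNA gene AT1G06237 (chromosome 1, 10300534 to 10300564, plus strand) took 0.744% of control reads and 2.17%, 2.34% and 3.60% of the nitrogen deficiency, drought and combined libraries, 4.84 times the control share in the last. A 16-nt sequence with no annotated feature, on chromosome 2 (12333099 to 12333114 and 12335059 to 12335074, minus strand) near AT2G28755, took 8.09% of control reads and 19.2%, 16.3% and 10.1% of the others, although it is shorter than the 18 nt at which the selected inserts begin. In the 24-nt class, reads from the nuclear genome outside annotated small RNA genes made up 32.0% in the control and 58.0%, 40.4% and 54.7% in the stressed libraries. In the authors' deposited quality sheets miRNA took 2.27%, 7.24%, 4.92% and 4.74% of reads in the same order.

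The miRNA share of reads under nitrogen deficiency was 3.31 times that in the control. With rRNA and tRNA reads left out the ratio was 1.92 (interval 1.90 to 1.93), which argues against dilution by rRNA and tRNA fragments as the whole cause, though part of the 3.31 went with them. Per 24-nt read elsewhere in the nuclear genome the ratio was 1.71 (1.69 to 1.73). On this measure combined stress stood at 0.937 against the control and 0.441 against drought. These values cannot decide whether the control held fewer Dicer-made small RNAs of all kinds. The 24-nt reads may include fragments not made by Dicer, and 49.3% began with A in the control against 58.3% under nitrogen deficiency. A larger part of such fragments in the control would raise the ratio of 1.71. Whether nitrogen deficiency had the same effect in the presence of PEG stays open, since combined stress stood at 1.28 times (1.26 to 1.29) drought for hairpin reads and at 1.61 times (1.59 to 1.64) for exact mature sequences, with intervals that cover counting error alone. A property of the control library alone may remain, as may an effect of nitrogen deficiency, the same or different under PEG, and without replicates these were not separated.

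In the authors' deposited tables, sorted by p-value, 98 of 98 neighbouring pairs of names were in alphabetical order (100%), where 1000 shuffles gave a mean of 49.99% and at most 62.2%. Among the 35 pairs of different families 35 were in order (100%), which argues against family members that share reads and hence values. Names sorted apart from their values is a candidate explanation that the order of the authors' deposited tables meets, and no biological explanation was tested.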
